A study of Mus musculus with 14 samples.

How the data were processed

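Liver RNA of 14 male C57BL/6 mice, 1 mouse per array, was hybridized to Affymetrix whole-transcript arrays. Per the labels, total RNA was isolated with RNeasy columns and 400 ng was made into biotin-labelled cDNA with the WT Plus kit. The deposited values are log2 intensities per probe set after RMA, which corrects background, normalizes quantiles of probes and summarizes them by median polish. The authors' notes name RMA and limma without versions, and whether arrays were adjusted for batch is not given in the sources used here. The scanner output was not used here. The median log2 value of an array lay between 2.21 and 2.30 over all probe sets, with a highest value near 13.6, so no further scaling was applied.

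Arrays were grouped by the number of floxed Lmna copies and by diet into 5 groups, with 2 arrays for WT on chow and 3 for each other group. Of 41345 probe sets, 23521 carried 1 gene symbol, 1814 carried several and 16010 none. Only those with 1 symbol were tested, and for the 1082 genes with several probe sets the brightest on average was kept, which left 22180 genes with no filter on level. Among the genes named for the largest rises or falls of a contrast, 9 such changes belong to genes with a second probe set. In 8 of these 9 the second, mostly dim probe set did not pass in the same direction. Changes of genes named only as list members were not compared with a second probe set. Arrays can also carry signal from close relatives, so the values of Hsd3b2, Hsd3b3 and Hsd3b5, of Cyp3a11 and Cyp3a59, of Orm2 and Orm3 and of Cyp4a12a and Cyp4a12b may not be separate measurements.

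Differences were tested with limma 3.58.1 in R 4.3.3. A model with 1 mean per group was fitted to all 14 arrays, with 9 residual and 3.83 prior degrees of freedom. The 8 contrasts were KO against HET, KO against WT and HET against WT on chow, KO against HET on HFD, the mean of KO minus HET over both diets, HFD against chow in HET and in KO, and the interaction of genotype and diet. P values were adjusted by the method of Benjamini and Hochberg over all genes within a contrast, and a gene was called at an adjusted p under 0.05. Age could not be separated from genotype, because all KO mice were older than all HET mice on the same diet.

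In total 32 gene lists were written down before the data were examined, as were the groups, contrasts, tests and the rule for naming genes. They cover the nuclear lamina, growth hormone signalling, male-biased and female-biased genes, fatty acid and triglyceride synthesis, cholesterol synthesis, lipid droplets, fatty acid oxidation, glucose metabolism, bile acids, xenobiotic metabolism, NRF2 targets, extracellular matrix, p53, cell cycle, interferon-stimulated genes, chemokines and NF-kB, acute phase proteins, endoplasmic reticulum stress, YAP and SRF targets, hepatocyte identity, pericentral and periportal genes, fetal genes and the clock. Marker lists cover stellate cells, macrophages, lymphocytes, neutrophils, endothelium, cholangiocytes, and fat, pancreas and red cells. The lists on growth hormone, sex bias, fibrosis and inflammation are themes already known for this mouse line and so were not chosen blind. Of 707 list entries 635 were measured. Lists were tested with camera at a preset correlation between genes of 0.01, again with the correlation estimated from the residuals, and with fry, adjusted over the 32 lists within a contrast. The preset value is lower than many estimated ones and gives smaller p values, and fry asks whether members changed at all and not whether they changed more than other genes.

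Named genes are Lmna, the 12 genes with the largest rise and the 12 with the largest fall per contrast among called genes whose groups do not overlap, and up to 4 members per list with the smallest p. Predicted genes, clone names, small RNAs and receptor segments were left out, and a gene named in 1 contrast may be named in others. Where fewer than 3 genes passed, the 6 with the smallest p are given. Members that moved against their list, and Clec4f and Cd5l for KO against HET, were named after their values were seen.

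Alternatives set before the data were examined were array weights, a trended and robust variance prior, a filter on dim probe sets, the mean of a gene's probe sets, all probe sets, a fit of only the groups compared, centring on the median, a second quantile normalization, the letter of the array name as a random block (shared within a group by F1 and F2, H1 and H2, B1 and B2, and C2 to C4, and never between groups), age as a linear term, a fold minimum of 1.5, an adjusted p under 0.01, chow controls as 1 group, and leaving out each array in turn. Chosen after seeing the data were leaving out HET arrays F1 and F2 together and a clock term, the Dbp minus Arntl difference of each array. The procedure was tested on simulated data with the arrays of KO against HET on HFD, where of 50 genes changed by 1 on the log2 scale 84% were called, and of those changed by 2, 3 and 4, 98%, 100% and 100%. Of 21980 unchanged simulated genes 12 were called, all 5 lists of 20 genes shifted by 0.5 passed, and no unshifted list did. The simulated genes varied independently and the lists were random, so false list calls from correlated genes were not tested.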

Results

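Gene expression was measured on 14 arrays of liver RNA from male C57BL/6 mice, 1 liver per array. All mice carried Alb-Cre, a transgene that makes Cre recombinase in hepatocytes under the albumin promoter. They differed in the number of floxed, Cre-removable copies of Lmna, the gene of the nuclear lamina proteins lamin A and lamin C. Mice with no floxed copy are called WT here, mice with 1 floxed copy HET and mice with 2 floxed copies KO. On standard chow there were 2 WT, 3 HET and 3 KO livers. A further 3 HET and 3 KO mice had been fed the Surwit diet, which is rich in fat and sucrose, for 14 weeks. Their drinking water held 42 g/L of carbohydrate, 55% of it fructose and 45% sucrose, and this regimen is called HFD here. The groups were not matched for age. WT mice were 24.6 and 27 weeks old and HET mice on chow 24 to 26.4 weeks, while KO mice on chow were 38.9 weeks old. These are the ages of the sample labels, whereas the series description starts the range at 26 weeks. On HFD the HET mice were 30 to 30.4 and the KO mice 35.3 weeks old. KO mice were thus 13.3 weeks older than HET mice on chow and 5.17 weeks older on HFD, on average, and this age gap stands behind every KO comparison. With 2 or 3 arrays per group the number of arrays limits the precision, most of all for WT with its 2 arrays. Values are log2 intensities, and a change is a difference of group means with ± giving its standard error from limma.

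Lmna itself was read by a single, dim probe set, and its level was lowest in the KO groups. It stood at 4.47 ± 0.05 (SD, n = 2) in WT and 4.31 ± 0.08 (SD, n = 3) in HET livers on chow, and at 3.85 ± 0.22 (SD, n = 3) in KO livers on chow. On HFD it was 4.15 ± 0.13 in HET and 3.99 ± 0.09 in KO livers (SD, n = 3 each). The chow change against WT passed the threshold (-0.62 ± 0.14, adjusted p = 0.0393), and the change against HET on chow did not (-0.47 ± 0.12, adjusted p = 0.0823). On HFD the KO and HET ranges overlapped, at 3.90 to 4.07 against 4.07 to 4.30, and the change was -0.16 ± 0.12, adjusted p = 0.517. Averaged over both diets, the KO minus HET change was -0.31 ± 0.09, adjusted p = 0.0386. The HET and WT chow livers were not told apart (-0.15 ± 0.14, adjusted p = 0.999). Which exon was floxed and where this probe set lies were not given in the sources used here, and liver cells other than hepatocytes keep their Lmna, so the values are a partial check of the labels. The other members of the nuclear lamina list, which holds the lamins and the proteins that anchor them, were not called on HFD. The list had 0 up and 0 down of 15, 0 and 0 adjusted over the list alone (camera adjusted p = 0.555, and adjusted p = 0.564 with an estimated correlation). Xist and Y-linked transcripts were as in male tissue in 14 of 14 arrays. The call of Lmna against WT was lost without single arrays, with the adjusted p in brackets: Lmna (0.0513 to 0.19 without G1, N1, F1, F2, H2, I1, A2, B1, C2, C3 or C4). So was the call over both diets: Lmna (0.0511 to 0.1 without F1, F2, H2, I1, A2, B1, B2, C2 or C4). The chow change against HET gained a call: Lmna (0.0253 without H1). Arrays of the same group correlated at 0.989 to 0.994 over the genes tested and arrays of different groups at 0.980 to 0.994, and none was close enough to another to be a duplicate. WT N1 correlated more with HET P1 (0.994) than with WT G1 (0.992), and WT G1 more with HET F1 and F2 (0.993 each) than with N1, so the chow controls did not group by genotype. The first principal component, with 36.1% of the variance, placed all 6 KO arrays apart from the 8 others.

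**Figure D1:**
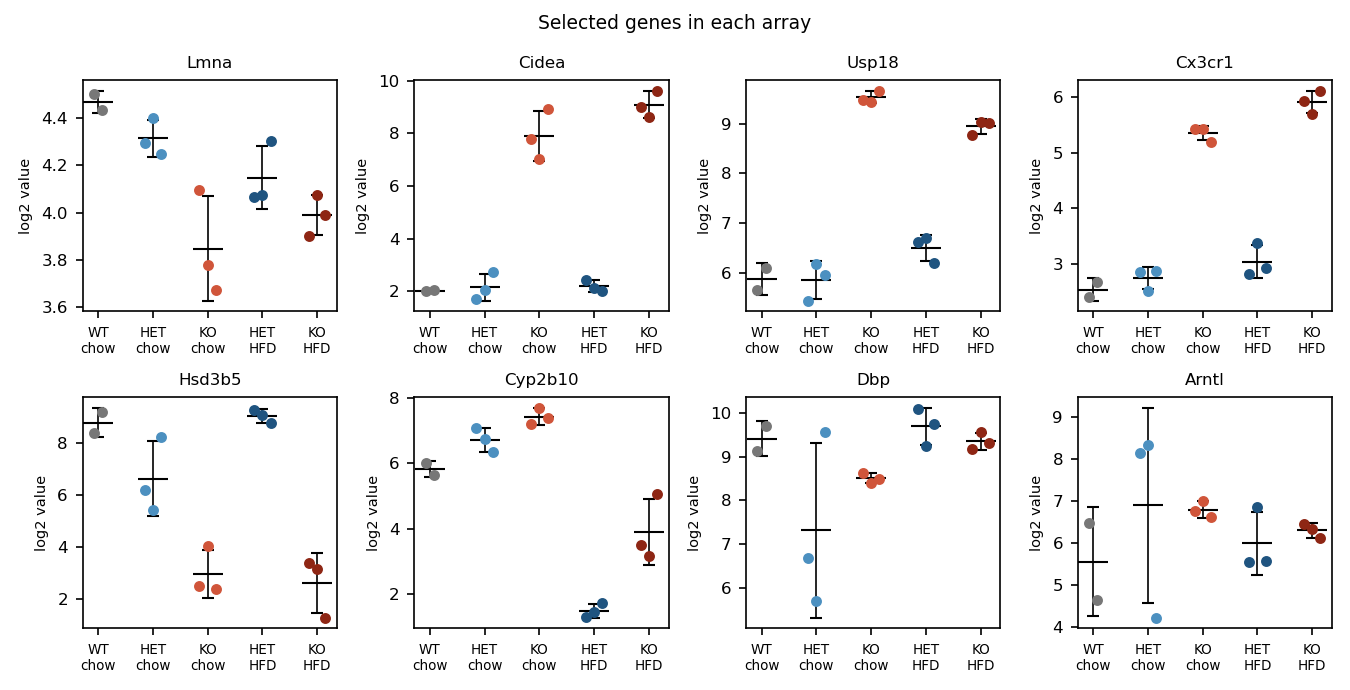
Log2 values (vertical axis) of 8 genes in each of the 14 arrays, by group (horizontal axis). Dots are arrays and bars the group mean and SD, and Cidea lies at 7.03 to 9.63 in the 6 KO arrays, while Dbp and Arntl split the 3 HET arrays on chow.

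In chow-fed mice the comparison asked how KO livers differ from HET livers. KO livers held more transcripts of interferon-stimulated genes, and the other lists that passed lost their call with an estimated correlation. Cidea, a lipid droplet protein normally scarce in lean liver, showed the largest rise (5.76 ± 0.40), from 2.16 ± 0.51 to 7.92 ± 0.95 (SD, n = 3 each). Its HET values lie near the array medians of 2.21 to 2.30, so the size of this rise is uncertain. Hsd3b5, a steroid dehydrogenase typical of male mouse liver, showed the largest fall (-3.68 ± 0.69), but with age as a linear term its change was 5.62 and did not pass. Its values in KO H1 (2.47) and I1 (2.35) lay near the array medians, so the size of this fall is uncertain too. In all, 426 of 22180 genes passed limma's adjusted p threshold of 0.05, 320 higher and 106 lower in KO, and 232 of them changed at least 2-fold. A call lost without single arrays, with the adjusted p in brackets, was that of Hsd3b5 (0.0506 to 0.0798 without H1 or I1).

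Interferon-stimulated genes moved most as a group between KO and HET livers on chow. Of this list, 20 of 22 measured members rose and 0 fell over all genes. These became 21 and 0 adjusted over the list alone (camera adjusted p = 7.52e-53; adjusted p = 3.05e-04 with an estimated correlation). Examples are Oasl2 (4.05 ± 0.27), Usp18, a deubiquitinase that removes Isg15 (3.66 ± 0.19), Ifit1 (3.54 ± 0.26), Irf7 (3.08 ± 0.18) and Isg15 itself (2.69 ± 0.17). The interferon-inducible Ifi27l2b rose by 4.17 ± 0.25 and the ubiquitin-like Ubd by 3.78 ± 0.35. For the lipid droplet and lipid uptake list, 5 of 23 measured members rose and 0 fell over all genes. There were 7 and 0 adjusted over the list alone (camera adjusted p = 1.34e-09; adjusted p = 0.0571 with an estimated correlation). Besides Cidea these were led by its relative Cidec (3.82 ± 0.57), the fatty acid transporter Cd36 (1.38 ± 0.15) and the acyltransferase Mogat1 (2.13 ± 0.33). Among targets of NRF2, the regulator of antioxidant genes, 5 of 17 rose and 0 fell (7 and 0 adjusted over the list alone). The cystine transporter Slc7a11 rose by 2.94 ± 0.36 and Nqo1 by 1.33 ± 0.22. For Slc7a11 a second, dimmer probe set was not compared on chow, and on HFD it stood at 0.10 and did not pass. The NRF2 list passed with the preset correlation but not with an estimated one (camera adjusted p = 1.54e-07, and adjusted p = 0.0641 with an estimated correlation). Of the cell cycle list, 8 of 29 measured members rose and 0 fell over all genes. This made 18 and 1 adjusted over the list alone (camera adjusted p = 3.60e-16; adjusted p = 0.0571 with an estimated correlation), with Cdc20 at 1.84 ± 0.25 and Nusap1 at 1.43 ± 0.16. Mogat1, Slc7a11 and Nusap1 had HET means below the array medians, so the sizes of their rises are uncertain. A linear age term turned Nqo1 to -1.09 and the NRF2 list to a mean of -0.13, and neither passed.

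Macrophage markers did not move as one between KO and HET livers on chow. In that list 4 of 24 measured members rose and 1 fell over all genes. It was 8 and 1 adjusted over the list alone (camera adjusted p = 4.56e-06; adjusted p = 0.288 with an estimated correlation). Its level was 0.46 in HET F1 and 0.31 in KO H1, so the 2 groups overlapped. Cx3cr1 (2.61 ± 0.17), Ly6c2 (2.63 ± 0.36) and Trem2 (1.42 ± 0.23), which mark recruited macrophages and monocytes, rose, while Timd4, a marker of resident Kupffer cells, fell (-1.52 ± 0.22). Other Kupffer cell markers, Clec4f (0.19 ± 0.18, adjusted p = 0.729) and Cd5l (-0.08 ± 0.23, adjusted p = 0.928), did not pass. In HET livers Ly6c2 lay below the array medians, which leaves the size of its rise uncertain. Markers of other cell types stood beside these as follows. The endothelial list had 0 up and 0 down of 18, 0 and 0 adjusted over the list alone (camera adjusted p = 0.671), the lymphocyte list 0 up and 0 down of 19, 0 and 0 adjusted over the list alone (camera adjusted p = 0.773) and the hepatic stellate cell list 0 up and 1 down of 17, 4 and 2 adjusted over the list alone (camera adjusted p = 0.172). The neutrophil list had 0 up and 0 down of 14, 0 and 0 adjusted over the list alone (camera adjusted p = 0.457), and that of fat, pancreas and red cells 0 up and 0 down of 11, 1 and 0 adjusted over the list alone (camera adjusted p = 0.49). The cholangiocyte list was higher with the preset correlation only (camera adjusted p = 9.81e-04, and adjusted p = 0.153 with an estimated correlation; 0 up and 0 down of 14, 3 and 0 adjusted over the list alone). Extracellular matrix genes were higher, since 5 of 32 measured members rose and 0 fell over all genes. The counts were 8 and 0 adjusted over the list alone (camera adjusted p = 1.02e-08; adjusted p = 0.153 with an estimated correlation), including the proteoglycan lumican (Lum, 1.34 ± 0.19). The level of this matrix list was 0.46 in HET F1 and 0.38 in KO H1, so here too the groups overlapped. Male-biased genes were lower as a list (camera adjusted p = 3.08e-04, and adjusted p = 0.0957 with an estimated correlation), and 1 of 22 rose and 3 fell (2 and 9 adjusted over the list alone). The member that rose, Cyp4a12a (1.08 ± 0.21), is a male-specific fatty acid hydroxylase and so ran against the other members. Female-biased genes were higher (camera adjusted p = 0.00114, and adjusted p = 0.0641 with an estimated correlation), and 2 of 29 rose and 0 fell (3 and 0 adjusted over the list alone), the called members being Gas6 (0.97 ± 0.19) and Cd36. Igf1 (-0.58 ± 0.12) and Igfals (-0.80 ± 0.17), both induced by growth hormone, fell, although the growth hormone signalling list as a whole did not pass (camera adjusted p = 0.063, and adjusted p = 0.153 with an estimated correlation; 0 up and 3 down of 16, 1 and 3 adjusted over the list alone). Lrat, a retinoid enzyme of stellate cells, was the member of its list that fell (-1.22 ± 0.23). Without single arrays calls were lost, at the adjusted p in brackets, for Cyp4a12a (0.0818 to 0.0944 without F1, H2 or I1), Gas6 (0.073 to 0.0924 without F1, F2 or I1) and Igf1 (0.0956 to 0.142 without F1, F2, H2 or I1). Also lost were Igfals (0.0695 to 0.121 without F2, P1, H2 or I1) and Lrat (0.0527 to 0.0657 without F1, F2 or I1). A call was gained for the hepatic stellate cell markers list (0.0143 without F1) and the growth hormone signalling list (0.0397 without F2). Under a linear age term the means of the extracellular matrix (-1.905, adjusted p = 0.0132), stellate cell (-1.86, adjusted p = 0.0195) and macrophage lists (-2.15, adjusted p = 0.00153) turned and passed the other way. The male-biased list (0.47) and Igfals (0.70) turned without passing. Without both HET arrays F1 and F2 the lymphocyte list turned to 0.32 and passed (adjusted p = 0.0354).

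The other genes with large changes on chow came from many families. Higher in KO than HET livers were the cell surface protein Ly6d (4.77 ± 0.28), the acute phase protein Orm3 (4.61 ± 0.95), Anxa13 (3.90 ± 0.30), the cytochrome Cyp2d12 (3.67 ± 0.46) and Apela, a peptide ligand of the apelin receptor (3.51 ± 0.35). For Cyp2d12 and Apela the HET values lay below the array medians, as did 1 HET array for Orm3, so these sizes are uncertain. Lower were the transcribed pseudogenes Adh6-ps1 (-3.61 ± 0.73) and Serpina4-ps1 (-3.38 ± 0.49), the complement-like C4a (-2.88 ± 0.32), the liver transcription factor Onecut1 (-2.78 ± 0.40) and the receptor Adgrf1 (-2.71 ± 0.46). Also lower were Etnppl (-1.81 ± 0.27), Steap2 (-1.78 ± 0.23), Albfm1 (-1.47 ± 0.23), Hsd3b3 (-1.39 ± 0.18) and the clock repressor Cry1 (-1.36 ± 0.29). In total 16 of the 32 lists passed camera, 14 higher and 2 lower, and 1 of them, the interferon list, also passed with an estimated correlation. The count of 426 depended on single arrays, falling to 258 without HET F1, 199 without HET F2, 215 without KO H2 and 202 without KO I1. The count became 143 without both HET arrays F1 and F2, a setting chosen after seeing the data. With age as a linear term 201 genes passed, 96 higher and 105 lower, and 8 of them were among the 426. Named calls lost without single arrays, with adjusted p in brackets, were Orm3 (0.0958 to 0.112 without F1, F2, H2 or I1), Adh6-ps1 (0.0688 to 0.112 without F1, F2, H2 or I1) and Adgrf1 (0.0527 without F2). Also lost was Cry1 (0.0503 to 0.147 without F1, F2, H2, I1 or C2).

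Against the 2 WT livers on chow, Cidea rose in KO livers by 5.89 ± 0.45 and the female-biased cytochrome Cyp2b9 by 6.37 ± 1.38, while Hsd3b5 fell by 5.85 on the log2 scale, from 8.80 ± 0.57 (SD, n = 2) to 2.95 ± 0.93 (SD, n = 3). Of 22180 genes 367 passed, 276 higher and 91 lower. Interferon-stimulated genes led again: 20 of 22 measured members rose and 0 fell over all genes. These became 21 and 0 adjusted over the list alone (camera adjusted p = 9.54e-57; adjusted p = 2.27e-04 with an estimated correlation). Among the genes higher by more than 3 on the log2 scale were Ifi27l2b (5.06 ± 0.28), Oasl2 (4.39 ± 0.31), Ubd (4.30 ± 0.40), Ly6d (4.23 ± 0.32), Cyp2d12 (4.0 ± 0.51), the actin bundler Pls1 (3.92 ± 0.69), Cidec (3.87 ± 0.64), Apela (3.78 ± 0.39), Oas1g (3.67 ± 0.53) and Usp18 (3.65 ± 0.22). The sizes for Cidea, Cyp2d12 and Apela are uncertain, since their WT values lay below the array medians, and so are those for Cyp2b9 and Oas1g, with 1 WT array there. Zfp872 had KO values near the medians, as did Hsd3b5 in KO H1 (2.47) and I1 (2.35), so the sizes of these falls are uncertain too. Lower were Adh6-ps1 (-5.23 ± 0.82), Serpina4-ps1 (-4.27 ± 0.55), Onecut1 (-3.51 ± 0.45), C4a (-3.13 ± 0.36), Adgrf1 (-3.09 ± 0.52), Selenbp2 (-2.30 ± 0.52), Foxq1 (-2.02 ± 0.35), Zfp872 (-1.93 ± 0.43), Clec2h (-1.89 ± 0.38), the urinary protein gene Mup21 (-1.79 ± 0.36) and Ugt2b38 (-1.74 ± 0.31). A second, dimmer probe set of Foxq1 stood at -0.20 and did not pass. Male-biased genes were lower, and 0 of 22 measured members rose and 7 fell over all genes. There were 0 and 10 adjusted over the list alone (camera adjusted p = 9.43e-09; adjusted p = 0.0228 with an estimated correlation). For female-biased genes 3 of 29 measured members rose and 0 fell over all genes. This made 11 and 1 adjusted over the list alone (camera adjusted p = 3.06e-05; adjusted p = 0.027 with an estimated correlation). For growth hormone signalling 0 of 16 measured members rose and 3 fell over all genes. It was 1 and 5 adjusted over the list alone (camera adjusted p = 0.00204; adjusted p = 0.0416 with an estimated correlation). Of the 16 lists that passed, 7 did so with an estimated correlation: the interferon, cell cycle, male-biased, female-biased, growth hormone, lipid droplet and NRF2 lists. The count fell to 232 without WT G1, 154 without WT N1, 244 without KO H2 and 213 without KO I1, and 162 genes passed when only the 5 arrays compared were fitted. With age as a linear term 124 genes passed, 4 of them among the 367. Clec2h (0.20), Foxq1 (0.25), Mup21 (0.91), Selenbp2 (2.57), Ugt2b38 (1.51), Zfp872 (1.78) and the male-biased list (0.06) then turned without passing. In fits without 1 array calls were lost, at the adjusted p in brackets, for Cyp2b9 (0.0508 to 0.232 without G1, N1, H1, H2, I1, C2 or C3), Pls1 (0.139 without N1) and Cidec (0.0763 without G1). Also lost were Adh6-ps1 (0.052 without G1), Adgrf1 (0.0943 without G1) and Selenbp2 (0.0524 to 0.27 without G1, N1, F1, H1, H2, I1, A2 or C2). Others lost were Foxq1 (0.144 without N1), Zfp872 (0.0543 to 0.398 without N1, F1, F2, P1, H1, H2, I1, A2, B1, B2 or C2) and Clec2h (0.0665 to 0.192 without G1, N1, H1 or I1). Next came Mup21 (0.0862 to 0.179 without G1, N1 or I1) and Ugt2b38 (0.172 without N1).

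Whether 1 floxed copy alone changed the liver was asked by HET against WT on chow. Under limma 0 genes passed the threshold, 954 genes had an unadjusted p under 0.05 and the number expected by chance is 1109. Nearest to the threshold was Spsb3 (0.94 ± 0.12, adjusted p = 0.0769). After it in order of p came Vmn1r2 (-1.21 ± 0.21), Mmp1b (-0.78 ± 0.14), the antiviral membrane protein Bst2 (0.69 ± 0.13), Pqlc3 (0.75 ± 0.14) and Ocel1 (-0.83 ± 0.16), with adjusted p of 0.357 to 0.448. Mmp1b in both groups, Vmn1r2 in HET and Pqlc3 in WT lay below the array medians of 2.21 to 2.30, so the sizes of these changes are uncertain. Male-biased genes were the 1 list of 32 that passed (camera adjusted p = 1.89e-04, and adjusted p = 0.255 with an estimated correlation), and in it 0 up and 0 down of 22, 0 and 0 adjusted over the list alone, with a mean change of -0.40. Hsd3b5 stood at 6.20 and 5.44 in HET arrays F1 and F2, at 8.25 in HET P1 and at 8.39 and 9.21 in WT. The same 2 HET arrays, which share the letter of their array name, also stood apart in clock genes. The clock output gene Dbp was at 6.68 and 5.70 in F1 and F2 against 9.56 in P1, and its counterphase partner Arntl at 8.13 and 8.35 against 4.22. The clock list did not pass (camera adjusted p = 0.22, and adjusted p = 0.629 with an estimated correlation; 0 up and 0 down of 16, 0 and 0 adjusted over the list alone). The count of 0 became 10 without HET P1, 2 without WT G1, and 1 each without KO H2 or HET HFD B1, and 6 genes passed without both F1 and F2. The 1 list became 6 without WT G1, 7 without HET P1 and 2 without N1, F1, A2 or B1. Calls gained in fits without 1 array, with adjusted p in brackets, were Spsb3 (0.029 to 0.0444 without P1 or B1), Vmn1r2 (0.0347 without H2) and the circadian clock and output genes list (0.00753 without P1).

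**Figure D2:**
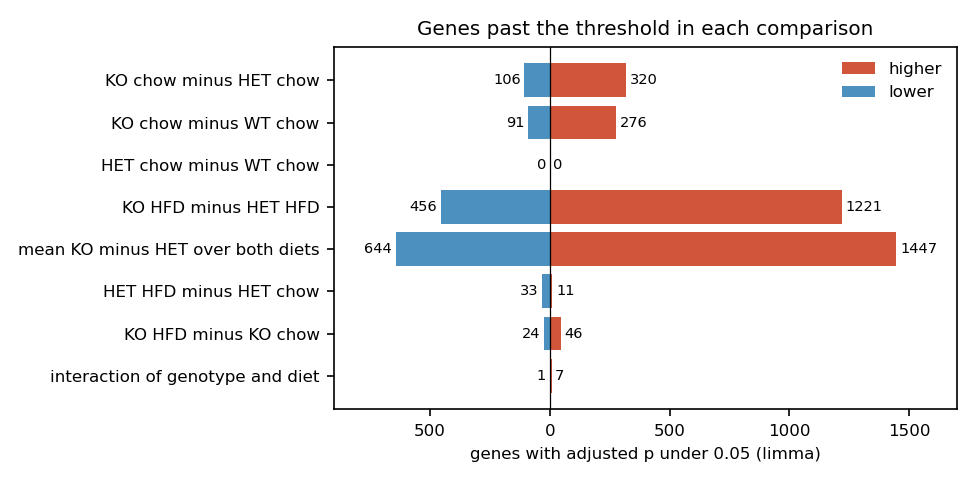
Number of genes past the threshold in each comparison (horizontal axis, genes with limma adjusted p under 0.05), higher to the right and lower to the left. KO against HET gave 1677 genes on HFD and 426 on chow, and HET against WT gave 0.

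On HFD, KO livers differed from HET livers in more genes than on chow. Cidea rose by 6.90 ± 0.40, a size left uncertain by HET values near the array medians, from 2.2 ± 0.22 to 9.10 ± 0.51 (SD, n = 3 each), and Hsd3b5 fell by 6.46 on the log2 scale, from 9.05 ± 0.26 to 2.59 ± 1.16, where KO C4 lay below the array medians, so this size is uncertain too. Genes of the NRF2 response, of cell division, of p53 targets and of extracellular matrix were higher, and genes of hepatocyte identity were lower. The threshold was passed by 1677 genes, 1221 higher and 456 lower, and 707 changed at least 2-fold. A test of whether the effect itself differed between the diets is given with the interaction, where 8 genes passed.

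Among metabolic groups on HFD, NRF2 targets stood out, because 12 of 17 measured members rose and 0 fell over all genes. The counts were 12 and 0 adjusted over the list alone (camera adjusted p = 1.42e-14; adjusted p = 0.0144 with an estimated correlation). Cbr3 (4.47 ± 0.53), Slc7a11 (4.26 ± 0.36), Nqo1 (3.38 ± 0.22) and Gstm3 (2.79 ± 0.19) rose most. HET values of Slc7a11, and of Mogat1 below, had means under the array medians, as did 1 HET array for Cbr3, so their sizes are uncertain. A second, dimmer probe set of Slc7a11 stood at 0.10 and did not pass. In the lipid droplet and uptake list 12 of 23 measured members rose and 0 fell over all genes. These became 13 and 0 adjusted over the list alone (camera adjusted p = 6.71e-10; adjusted p = 0.0245 with an estimated correlation), including Cidec (5.06 ± 0.57), Mogat1 (3.25 ± 0.33) and Cd36 (2.46 ± 0.15). For fatty acid oxidation and PPAR alpha targets 10 of 26 measured members rose and 0 fell over all genes. There were 14 and 0 adjusted over the list alone (camera adjusted p = 1.21e-08; adjusted p = 0.0915 with an estimated correlation), among them the thioesterase Acot2 (2.43 ± 0.33) and the peroxisomal enzyme Ehhadh (1.41 ± 0.12). Cholesterol synthesis genes were lower (camera adjusted p = 0.00163, and adjusted p = 0.431 with an estimated correlation), and 0 of 19 rose and 2 fell (0 and 6 adjusted over the list alone). The synthesis list for fatty acids and triglycerides (camera adjusted p = 0.0483, and adjusted p = 0.431 with an estimated correlation) and the bile acid list (camera adjusted p = 0.0483, and adjusted p = 0.375 with an estimated correlation) lay just past the threshold. In the first 0 up and 1 down of 20, 0 and 1 adjusted over the list alone, and in the second 2 up and 7 down of 19, 3 and 7 adjusted over the list alone, where the efflux pump Abcc4 rose by 3.47 ± 0.21. The xenobiotic list did not pass (camera adjusted p = 0.951, and adjusted p = 0.979 with an estimated correlation), and its members went both ways (5 up and 2 down of 26, 7 and 6 adjusted over the list alone). Ephx1 rose (1.22 ± 0.13) and the carboxylesterase Ces2a fell (-1.17 ± 0.12). The glucose list did not pass either (camera adjusted p = 0.0575, and adjusted p = 0.135 with an estimated correlation; 1 up and 2 down of 20, 2 and 6 adjusted over the list alone). Lists that lost their call without single arrays, with adjusted p in brackets, were the cholesterol synthesis and uptake list (0.072 to 0.0912 without A2 or B1), the fatty acid and triglyceride synthesis list (0.0527 to 0.3 without F2, B1, C3 or C4) and the bile acid synthesis and transport list (0.053 to 0.119 without F2, H1, A2, B1 or C4). A call was gained by the glucose metabolism and insulin response list (0.0178 to 0.0476 without P1 or C4). The xenobiotic list turned to 0.81 with age as a linear term and passed (adjusted p = 2.56e-04), and the list of fatty acid synthesis (0.14) turned without passing. For bile acids only the camera direction, relative to other genes, turned without passing, while the mean stayed negative (-0.10 without the term, -0.025 with it).

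Sex-biased genes shifted on HFD in both directions. In the male-biased list 2 of 22 measured members rose and 11 fell over all genes. This made 2 and 14 adjusted over the list alone (camera adjusted p = 3.41e-07; adjusted p = 0.0174 with an estimated correlation). Besides Hsd3b5, the organic anion transporter Slco1a1 (-2.78 ± 0.52), Mup21 (-2.28 ± 0.32), Serpina1e (-2.14 ± 0.17) and Selenbp2 (-2.13 ± 0.47) fell. Cyp4a12a (1.31 ± 0.21) and Cyp4a12b (1.15 ± 0.19) rose against the rest of the list. In the female-biased list 10 of 29 measured members rose and 1 fell over all genes. It was 14 and 3 adjusted over the list alone (camera adjusted p = 9.52e-06; adjusted p = 0.0157 with an estimated correlation), with Cyp2a4 at 3.47 ± 0.52 and Cyp2b10 at 2.41 ± 0.37, while Slco1a4 fell (-1.01 ± 0.28). The HET values of Cyp2b10 lay below the array medians, so its size is uncertain. Bcl6, a repressor of female-biased genes in male liver, fell (-2.65 ± 0.65). The growth hormone list did not pass (camera adjusted p = 0.117, and adjusted p = 0.198 with an estimated correlation; 1 up and 2 down of 16, 1 and 4 adjusted over the list alone). Hepatocyte identity genes were slightly lower, and 0 of 19 measured members rose and 5 fell over all genes. The counts were 0 and 7 adjusted over the list alone (camera adjusted p = 3.62e-05; adjusted p = 0.0144 with an estimated correlation), with Cps1, the first enzyme of the urea cycle, at -0.53 ± 0.09. Pericentral genes passed with the preset correlation only (camera adjusted p = 0.0331, and adjusted p = 0.502 with an estimated correlation; 1 up and 1 down of 14, 2 and 5 adjusted over the list alone), where the vasopressin receptor Avpr1a fell (-2.2 ± 0.38) and the ammonium transporter Rhbg rose (3.11 ± 0.33). Periportal genes did not pass (camera adjusted p = 0.426, and adjusted p = 0.67 with an estimated correlation; 2 up and 1 down of 11, 2 and 2 adjusted over the list alone). Leaving out 1 array ended calls, at the adjusted p in brackets, of Selenbp2 (0.0542 to 0.0675 without B2 or C4), Slco1a4 (0.0513 to 0.115 without F2, H2, I1, A2, B1, B2, C3 or C4) and Bcl6 (0.0562 to 0.088 without A2, B2, C2, C3 or C4). Also lost was the pericentral genes list (0.0751 to 0.21 without A2, B1 or C4). Bcl6 (0.82), Cyp4a12b (-0.029) and the pericentral list (0.17) turned with age as a linear term, without passing.

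Immune, stromal and growth-related groups were mostly higher in KO livers on HFD. Of interferon-stimulated genes 16 of 22 measured members rose and 0 fell over all genes. These became 17 and 0 adjusted over the list alone (camera adjusted p = 2.76e-21; adjusted p = 0.0105 with an estimated correlation), with Usp18 at 2.44 ± 0.19. The cell cycle list had 19 up and 1 down of 29, 22 and 1 adjusted over the list alone (camera adjusted p = 1.08e-18, and adjusted p = 0.0174 with an estimated correlation), with Ccnb2 at 2.38 ± 0.29, and the member that fell was the thymidine kinase Tk1. For p53 and DNA damage genes 11 of 21 measured members rose and 0 fell over all genes. There were 12 and 0 adjusted over the list alone (camera adjusted p = 5.19e-09; adjusted p = 0.033 with an estimated correlation), led by the cell cycle inhibitor Cdkn1a (3.92 ± 0.64), Tnfrsf10b (2.54 ± 0.33) and Eda2r (2.49 ± 0.28), the last from a HET mean near the array medians and so of uncertain size. Extracellular matrix genes showed 13 up and 1 down of 32, 25 and 1 adjusted over the list alone (camera adjusted p = 1.16e-14, and adjusted p = 0.0482 with an estimated correlation), with Tgfb2 at 1.60 ± 0.17 and the collagen Col3a1 at 1.46 ± 0.23, while fibronectin (Fn1) fell (-0.38 ± 0.10). In the macrophage list 9 of 24 measured members rose and 1 fell over all genes. This made 15 and 1 adjusted over the list alone (camera adjusted p = 3.27e-10; adjusted p = 0.129 with an estimated correlation). Cx3cr1 rose by 2.87 ± 0.17 and Trem2 by 1.85 ± 0.23, while Timd4 fell (-1.39 ± 0.22), as did Cd163, a scavenger receptor of resident macrophages outside the list (-2.46 ± 0.45). Clec4f (0.00 ± 0.18, adjusted p = 0.997) and Cd5l (0.30 ± 0.23, adjusted p = 0.501), further Kupffer cell markers, did not pass. Chemokines and NF-kB targets were higher, and 9 of 25 measured members rose and 0 fell over all genes. It was 18 and 0 adjusted over the list alone (camera adjusted p = 9.53e-10; adjusted p = 0.0378 with an estimated correlation), with the receptor Tlr2 at 1.14 ± 0.20 and Tnfaip3 at 1.88 ± 0.43. For cholangiocyte and ductular markers 4 of 14 measured members rose and 0 fell over all genes. The counts were 7 and 0 adjusted over the list alone (camera adjusted p = 2.99e-06; adjusted p = 0.0378 with an estimated correlation), led by Sox4 (3.15 ± 0.27). Actin and YAP or SRF targets had 7 up and 0 down of 21, 8 and 0 adjusted over the list alone (camera adjusted p = 7.71e-08, and adjusted p = 0.0643 with an estimated correlation), with Anxa2 at 2.31 ± 0.24. The list of fetal and tumour-associated genes had 3 up and 0 down of 12, 4 and 0 adjusted over the list alone (camera adjusted p = 1.16e-04, and adjusted p = 0.0747 with an estimated correlation), with Ly6d at 5.69 ± 0.28. Calls of Fn1 (0.0684 to 0.11 without A2, B1, C3 or C4) and Tnfaip3 (0.0727 to 0.0753 without B1 or C4) ended without single arrays, at the adjusted p in brackets. The macrophage list turned to -0.11 with a linear age term and did not pass.

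Lists of further cell types were given on HFD as measured. Lymphocyte markers were higher with the preset correlation (camera adjusted p = 1.23e-04, and adjusted p = 0.127 with an estimated correlation; 2 up and 0 down of 19, 4 and 0 adjusted over the list alone). Endothelial (camera adjusted p = 0.185, and adjusted p = 0.337 with an estimated correlation; 1 up and 1 down of 18, 1 and 1 adjusted over the list alone) and stellate cell markers (camera adjusted p = 0.182, and adjusted p = 0.564 with an estimated correlation; 2 up and 2 down of 17, 5 and 2 adjusted over the list alone) did not pass. Neutrophil markers (camera adjusted p = 0.876, and adjusted p = 0.914 with an estimated correlation; 0 up and 0 down of 14, 0 and 0 adjusted over the list alone) and markers of fat, pancreas and red cells (camera adjusted p = 0.95, and adjusted p = 0.948 with an estimated correlation; 1 up and 0 down of 11, 1 and 0 adjusted over the list alone) did not pass either. Acute phase proteins (camera adjusted p = 0.157, and adjusted p = 0.544 with an estimated correlation; 4 up and 0 down of 22, 5 and 2 adjusted over the list alone), among which lipocalin 2 rose (Lcn2, 3.24 ± 0.49), endoplasmic reticulum stress genes (camera adjusted p = 0.819, and adjusted p = 0.948 with an estimated correlation; 0 up and 0 down of 22, 0 and 0 adjusted over the list alone) and clock genes (camera adjusted p = 0.0562, and adjusted p = 0.134 with an estimated correlation; 0 up and 0 down of 16, 0 and 0 adjusted over the list alone) also missed the threshold. A call gained without single arrays, with adjusted p in brackets, was that of the circadian clock and output genes list (0.022 to 0.0487 without G1, N1, F2, P1 or B2). The lymphocyte list turned to -0.24 with age as a linear term and did not pass.

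Single genes with large changes on HFD otherwise included Apela (5.47 ± 0.35), Elapor1 (5.08 ± 0.52), Ubd (4.95 ± 0.35), the trypsin inhibitor Spink1 (4.54 ± 0.75), Anxa13 (4.47 ± 0.30), Ifi27l2b (4.46 ± 0.25) and the zinc importer Slc39a4 (4.21 ± 0.46). Apela and Spink1 had HET means below the array medians, and the sizes of their rises are uncertain. Lower were Adgrf1 (-4.03 ± 0.46), Adh6-ps1 (-3.36 ± 0.73), Hsd3b2 (-2.17 ± 0.32) and C4a (-2.05 ± 0.32). Of the 20 lists that passed, 11 did so with an estimated correlation. The count of 1677 fell to 1038 without KO C2 and 971 without KO C4, and a second quantile normalization split 1667 calls into 954 higher and 713 lower. A call lost without single arrays, with adjusted p in brackets, was that of Adh6-ps1 (0.0556 to 0.0646 without A2, B1, C2 or C3). With age as a linear term 249 genes passed, 77 of them also in the fit without it, although age varied within 3 of the groups by at most a few weeks.

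**Figure D3:**
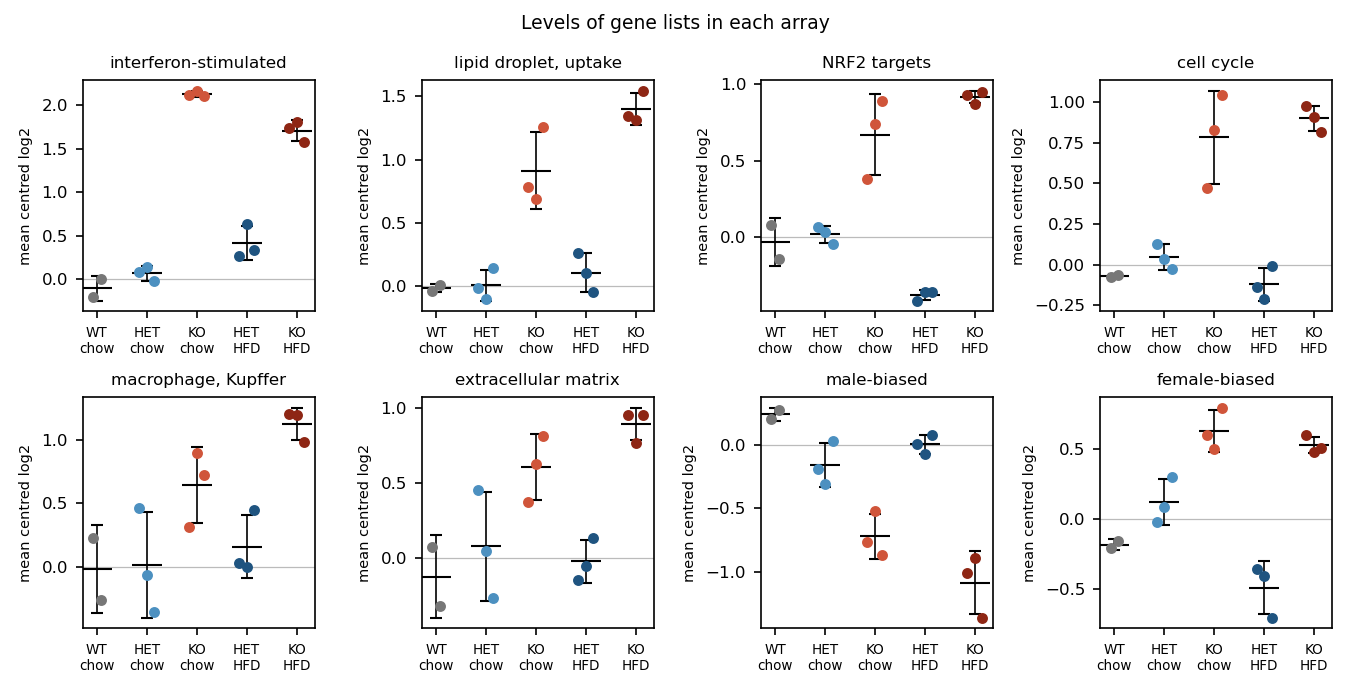
Level of 8 gene lists in each of the 14 arrays (vertical axis, mean log2 value of the members minus the mean of the 5 WT and HET arrays on chow), by group (horizontal axis). Dots are arrays and bars the group mean and SD, and the interferon list lies at 2.13 ± 0.03 in KO on chow and 1.71 ± 0.12 in KO on HFD.

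Taking the KO minus HET change over both diets together, with 6 against 6 arrays, gave the largest count. Cidea (6.33 ± 0.28), Ly6d (5.23 ± 0.20), Apela (4.49 ± 0.24), Cidec (4.44 ± 0.40), Ubd (4.36 ± 0.25), Ifi27l2b (4.31 ± 0.18) and Anxa13 (4.19 ± 0.22) led the rises. Orm3 (4.09 ± 0.67), Cbr3 (3.66 ± 0.37), Slc7a11 (3.60 ± 0.26), Elapor1 (3.52 ± 0.37) and Pls1 (3.42 ± 0.44) followed. Of these, Cidea, Apela and Slc7a11 had HET means below the array medians of 2.21 to 2.30 on both diets, which leaves their sizes and order uncertain, and single HET arrays of Orm3 and Cbr3 lay there too. For Slc7a11 a second, dimmer probe set stood at 0.11 and did not pass. Hsd3b5 (-5.07 ± 0.49), Adh6-ps1 (-3.48 ± 0.52), Adgrf1 (-3.37 ± 0.33), Serpina4-ps1 (-2.64 ± 0.34) and C4a (-2.47 ± 0.23) led the falls, with Cd163 (-2.08 ± 0.32), Selenbp2 (-1.86 ± 0.33), Hsd3b2 (-1.72 ± 0.23), Steap2 (-1.61 ± 0.17), Etnppl (-1.54 ± 0.19), the synaptic scaffold gene Pclo (-1.49 ± 0.26) and Hsd3b3 (-1.49 ± 0.13) after them. The KO means of Pclo and the value of Hsd3b5 in KO C4 lay below the array medians, so these sizes are uncertain. Under a linear age term Hsd3b5 (1.39), Selenbp2 (1.57) and Cd163 (0.03) turned without passing. The threshold was passed by 2091 genes, 1447 higher and 644 lower. In the interferon list 21 of 22 measured members rose and 0 fell over all genes. These became 21 and 0 adjusted over the list alone (camera adjusted p = 5.52e-37; adjusted p = 0.00129 with an estimated correlation). In the cell cycle list 23 of 29 measured members rose and 1 fell over all genes. There were 24 and 1 adjusted over the list alone (camera adjusted p = 1.39e-21; adjusted p = 0.0162 with an estimated correlation), and the member that fell was again Tk1. Of the 18 lists that passed, 11 also passed with an estimated correlation.

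The genotype effect ran the same way on both diets for most called genes. Of the 320 genes higher in KO on chow, 240 were also called higher on HFD, where independent lists would share 17.6, and of the 106 lower genes 42 were also called lower, against 2.18. Across 22180 genes the KO minus HET changes on the 2 diets, which share no array, correlated with Pearson r of 0.591 (jackknife SE 0.126) and Spearman rho of 0.323. Genes are not independent replicates. Another pair of contrasts with no array in common, KO against HET on HFD and HET against WT on chow, gave r = 0.160. A second quantile normalization split 2197 calls into 1208 higher and 989 lower, and centring on the median split 2206 into 1779 and 427. With age as a linear term 211 genes passed for the mean over both diets, 37 of them shared with the fit without it.

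**Figure D4:**
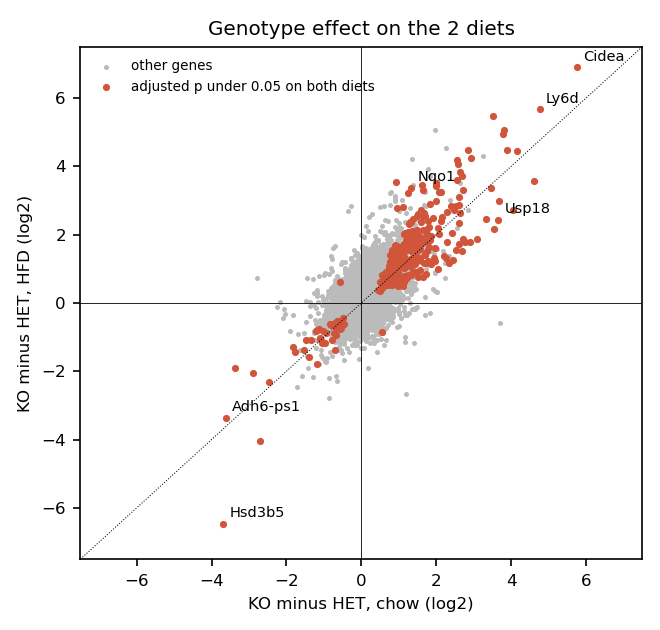
Change between KO and HET livers on chow (horizontal axis, log2) against that on HFD (vertical axis, log2) for all 22180 genes. Red dots passed on both diets, and the dotted line marks equal changes, with Cidea at 5.76 and 6.90, and Hsd3b5 at -3.68 and -6.46.

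In HET livers the diet effect was asked by HFD against chow. The cytochrome Cyp2b10 fell by 5.22 on the log2 scale, from 6.72 ± 0.37 to 1.5 ± 0.21 (SD, n = 3 each), and as its values on HFD lay below the array medians of 2.21 to 2.30, the size of this fall is uncertain. Cyp2c55 (-3.69 ± 0.36), Cyp3a59 (-2.32 ± 0.38) and Cyp3a11 (-2.22 ± 0.23) fell too. A second, dimmer probe set of Cyp2c55 stood at 0.24 and did not pass. Apoa4, an apolipoprotein of fat-loaded liver and gut, rose by 3.14 ± 0.31, and the fasting and sugar-responsive hormone gene Fgf21 by 2.59 ± 0.45. In all 44 genes passed, 11 higher and 33 lower. The other called rises included Arrdc3 (2.07 ± 0.36), the water channel Aqp4 (1.73 ± 0.21), Omd (1.71 ± 0.30), Tnfaip8l1 (1.51 ± 0.13), Tmie (1.14 ± 0.20), Fam13a (0.98 ± 0.13), the fructose kinase Khk (0.85 ± 0.14) and Hykk (0.83 ± 0.14). Lower were Ect2 (-2.04 ± 0.29), Gstm3 (-1.81 ± 0.19), the transporter Slco1a4 (-1.69 ± 0.28), Etnppl (-1.65 ± 0.27), Slc16a5 (-1.40 ± 0.20), Nqo1 (-1.33 ± 0.22), Fgfr1 (-1.28 ± 0.21) and Orm2 (-1.27 ± 0.23). HET mice on HFD were older than HET mice on chow, so age stands behind this comparison too. Calls ended by leaving out 1 array, with their adjusted p, were Cyp3a59 (0.0531 to 0.13 without F1, F2, H1, H2, C2, C3 or C4), Fgf21 (0.0516 to 0.152 without G1, N1, F1, F2, P1, H1, H2, A2, B1, B2, C2, C3 or C4) and Arrdc3 (0.0541 to 0.191 without F1, F2, H1, H2, I1, A2, B1, B2, C2, C3 or C4). Also lost were Omd (0.0541 to 0.151 without G1, N1, F1, F2, H1, H2, I1, A2, B1 or C2), Tmie (0.0582 to 0.152 without G1, N1, F1, H1, H2, I1, A2, B1, B2, C2, C3 or C4) and Fam13a (0.0533 to 0.0611 without F1 or F2). Others lost were Khk (0.0507 to 0.13 without F1, F2, H1, H2, I1, A2, B1, C2, C3 or C4), Hykk (0.0502 to 0.145 without F1, F2, H1, H2, I1, A2, B1 or C4) and Ect2 (0.0535 to 0.0789 without F2 or A2). Next came Slco1a4 (0.0516 to 0.132 without F1, F2, H1, H2, A2 or B1), Etnppl (0.0516 to 0.138 without F1, F2, H1, A2, B1, C2, C3 or C4) and Slc16a5 (0.0535 to 0.0789 without F1, F2 or A2). Further losses were Nqo1 (0.0581 to 0.134 without F1, F2, H2, A2, B1, B2 or C2), Fgfr1 (0.0516 to 0.123 without F1, F2, A2, B1, B2, C2 or C4) and Orm2 (0.058 to 0.192 without F1, F2, H1, H2, I1, B1, B2, C2, C3 or C4).

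By list, xenobiotic genes were lower on HFD in HET livers, and 0 of 26 measured members rose and 3 fell over all genes. This made 0 and 7 adjusted over the list alone (camera adjusted p = 1.63e-04; adjusted p = 0.402 with an estimated correlation). For NRF2 targets 0 of 17 measured members rose and 4 fell over all genes. It was 0 and 5 adjusted over the list alone (camera adjusted p = 2.39e-06; adjusted p = 0.0891 with an estimated correlation). Female-biased genes were lower too, and 0 of 29 measured members rose and 2 fell over all genes. The counts were 0 and 7 adjusted over the list alone (camera adjusted p = 4.67e-05; adjusted p = 0.0707 with an estimated correlation), the 2 called being Cyp2b10 and Slco1a4, which are also targets of the drug-sensing receptor CAR. Fatty acid and triglyceride synthesis genes were higher as a list, although 0 of 20 measured members rose and 0 fell over all genes. These became 9 and 0 adjusted over the list alone (camera adjusted p = 1.68e-08; adjusted p = 0.0891 with an estimated correlation). Pklr, a glycolytic enzyme, stood at 1.71 ± 0.32, adjusted p = 0.0556 and the carboxylase Acacb at 1.13 ± 0.22, adjusted p = 0.0644. The interferon list was also higher (camera adjusted p = 1.20e-06, and adjusted p = 0.0891 with an estimated correlation; 0 up and 0 down of 22, 5 and 0 adjusted over the list alone), as was the clock list (camera adjusted p = 0.00486, and adjusted p = 0.0891 with an estimated correlation; 0 up and 0 down of 16, 6 and 1 adjusted over the list alone), which moved with the clock split of the HET chow arrays. Of the 9 lists that passed, none kept its call with an estimated correlation. The count of 44 became 17 without HET F1, 13 without F2, 164 without P1, 22 without A2, 19 without B1, 23 without KO H1, 24 without H2, 22 without C2 and 24 without C3 or C4, and 3 genes passed when only the 6 arrays compared were fitted. A linear age term turned the xenobiotic list to 0.33, and it did not pass. Lost, with adjusted p in brackets, was the xenobiotic metabolism list (0.0515 to 0.103 without P1 or B2). Gained were Pklr (0.013 to 0.0274 without G1, N1 or P1) and Acacb (0.012 to 0.0368 without P1 or B2).

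Between KO livers on HFD and on chow, Cyp2b10 fell by 3.51 on the log2 scale, from 7.43 ± 0.25 to 3.91 ± 1.0 (SD, n = 3 each). Guca2b, which encodes the gut peptide uroguanylin, showed the largest rise (2.32 ± 0.24), from 2.96 ± 0.65 to 5.28 ± 0.14. There were 70 called genes, 46 higher and 24 lower. Higher were the acetyl-CoA synthetase Acss1 (2.2 ± 0.30), the mucin Muc13 (2.13 ± 0.29), Cyp21a1 (2.03 ± 0.34), the protease Ctse (1.99 ± 0.20), Tmem238l (1.84 ± 0.28), Fermt1 (1.82 ± 0.34), Serpinb9e (1.68 ± 0.27), the serine synthesis enzyme Psat1 (1.63 ± 0.25), Parm1 (1.57 ± 0.24), Morc4 (1.56 ± 0.19) and Lrrc8b (1.46 ± 0.24). Lower were Cyp2c55 (-2.44 ± 0.36), Cyp3a59 (-2.41 ± 0.38), Slco1a4 (-2.30 ± 0.28), Ces2a (-2.09 ± 0.12), Serpina1e (-1.82 ± 0.17), Cyp2c29 (-1.63 ± 0.18), Cyp3a11 (-1.47 ± 0.23), Igfbp2 (-1.24 ± 0.22), the antiviral Mx1 (-1.23 ± 0.17), Neb (-1.09 ± 0.20) and Rdh16f2 (-0.92 ± 0.17). The means of Tmem238l on chow and of Mx1 on HFD lay below the array medians, as did 1 chow array for Psat1, so their sizes are uncertain. Second, dimmer probe sets of Acss1, Cyp2c55 and Cyp2c29 stood at 0.30, -0.52 and 0.10 and did not pass. KO mice on HFD were younger than KO mice on chow. Calls that leaving out 1 array ended, with adjusted p, were Acss1 (0.061 without H1), Muc13 (0.061 without H1) and Cyp21a1 (0.0891 to 0.139 without H1, H2, C3 or C4). Also lost were Tmem238l (0.0672 to 0.101 without H1, H2 or C2), Fermt1 (0.0576 to 0.194 without G1, N1, F1, F2, H1, H2, A2, B1, B2, C2, C3 or C4) and Serpinb9e (0.096 to 0.113 without H1, H2, C2 or C4). Others lost were Psat1 (0.0862 to 0.101 without H1, H2, C2 or C4), Parm1 (0.0901 to 0.107 without H1 or H2) and Lrrc8b (0.0672 to 0.127 without H1, H2, C2, C3 or C4). Next came Cyp2c55 (0.0672 to 0.0941 without H1, H2, C2 or C3), Cyp3a59 (0.0672 to 0.113 without H1, H2, C2, C3 or C4) and Cyp3a11 (0.0859 to 0.111 without H1, H2, C3 or C4). Further losses were Igfbp2 (0.0501 to 0.158 without F1, H1, H2, A2, C2, C3 or C4), Neb (0.0501 to 0.188 without F1, F2, H1, H2, I1, A2, B1, B2, C2, C3 or C4) and Rdh16f2 (0.0556 to 0.184 without F1, F2, H1, H2, A2, B1, C2, C3 or C4).

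By list, the xenobiotic group was lower in KO livers on HFD, and 0 of 26 measured members rose and 4 fell over all genes. There were 0 and 9 adjusted over the list alone (camera adjusted p = 2.15e-08; adjusted p = 0.128 with an estimated correlation). Interferon-stimulated genes were lower, with 0 up and 1 down of 22, 0 and 5 adjusted over the list alone (camera adjusted p = 2.78e-08, and adjusted p = 0.128 with an estimated correlation). Macrophage markers were higher as a list, with 0 up and 0 down of 24, 9 and 0 adjusted over the list alone (camera adjusted p = 2.78e-08, and adjusted p = 0.279 with an estimated correlation), as were lipid droplet genes, with 0 up and 0 down of 23, 4 and 0 adjusted over the list alone (camera adjusted p = 7.24e-06, and adjusted p = 0.128 with an estimated correlation). Of the 18 lists that passed, 12 higher and 6 lower, none kept its call with an estimated correlation, and 10 passed without KO H1. The count of 70 became 13 without KO H1, 17 without H2, 119 without I1, 27 without C2, 21 without C3, 28 without C4 and 45 without HET F2.

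The diet effects in HET and KO livers had 6 lowered genes in common of 33 and 24, where independent lists would share 0.0357, and 0 raised genes of 11 and 46. Whether the genotype effect differed between diets was tested by the interaction, which 8 genes passed. The KO minus HET change was more positive on HFD than on chow for Slc16a5 (2.61 ± 0.28), Guca2b (2.45 ± 0.34), Nqo1 (2.05 ± 0.31), Gstm3 (1.82 ± 0.27), Pqlc3 (1.39 ± 0.18), the histone methyltransferase gene Kmt5a (1.25 ± 0.15) and Tmem79 (1.18 ± 0.17), and more negative for Tnfaip8l1 (-1.41 ± 0.19). The sign changed between chow and HFD for Kmt5a (-0.39 ± 0.11, adjusted p = 0.0933, and 0.86 ± 0.11), Tmem79 (-0.57 ± 0.12, and 0.62 ± 0.12) and Tnfaip8l1 (0.57 ± 0.13, and -0.84 ± 0.13). Guca2b and Pqlc3 had HET means on HFD below the array medians, so their sizes are uncertain. A second, dimmer probe set of Slc16a5 stood at 1.97 and did not pass (adjusted p = 0.0714). Nqo1 stood at 6.54 ± 0.21 and 5.21 ± 0.06 in HET livers on chow and HFD, and at 7.86 ± 0.40 and 8.58 ± 0.33 in KO livers (SD, n = 3 each). The interferon list was less raised on HFD than on chow, by -0.76 on average over its members, with 0 up and 0 down of 22, 0 and 9 adjusted over the list alone (camera adjusted p = 6.10e-14, and adjusted p = 0.0452 with an estimated correlation). The NRF2 list was more raised on HFD, by 0.64, with 2 up and 0 down of 17, 3 and 0 adjusted over the list alone (camera adjusted p = 1.77e-07, and adjusted p = 0.0895 with an estimated correlation). In all 19 lists passed, 12 higher and 7 lower, and 1 of them, the interferon list, with an estimated correlation, and 9 passed without KO H1. The count of 8 became 1 without HET F1, KO H1 or KO C2, 0 without HET F2 or KO H2, 43 without HET P1, 35 without KO I1 and 4 without HET A2 or KO C4, and each of the 8 genes lost its call without some arrays. With adjusted p in brackets these were Slc16a5 (0.0526 to 0.0533 without F2 or H2), Guca2b (0.0516 to 0.122 without F1, F2, H1, H2, A2, B1, B2, C2 or C4) and Nqo1 (0.075 to 0.152 without F1, F2, H1, H2, A2, B1, B2, C2 or C4). Also lost were Gstm3 (0.0655 to 0.134 without G1, N1, F1, F2, H1, H2, A2, B1, B2, C2, C3 or C4), Pqlc3 (0.0626 to 0.0969 without F1, F2, H1, H2, A2 or C2) and Kmt5a (0.0689 to 0.0889 without F1, F2, H1, H2 or C2). Others lost were Tmem79 (0.0648 to 0.134 without G1, N1, F1, F2, H1, H2, B1, C2, C3 or C4) and Tnfaip8l1 (0.0549 to 0.0969 without F1, F2, H1, H2, A2, B2, C2 or C4). On chow calls were lost for Tmem79 (0.0523 to 0.146 without F1, F2, P1, H1, H2, I1 or C2) and Tnfaip8l1 (0.0582 to 0.193 without G1, N1, F1, F2, H1, H2, I1, A2, B1, B2, C2, C3 or C4), and gained for Kmt5a (0.043 without P1).

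The genotype effect was also set against the diet effect. KO against WT on chow and HET on HFD against HET on chow, which share no array, correlated with r = -0.00451 (jackknife SE 0.0723) over 22180 genes. Of their called genes 1 was raised in both, of 276 and 11, where independent lists would share 0.137, and 2 were lowered in both, of 91 and 33, against 0.135 (Fisher exact p = 0.129 and 0.00809). The pair that shares the HET chow arrays, KO against HET on chow and HET on HFD against chow, gave r = 0.287. Simulated unchanged groups sharing arrays gave r = 0.5 and a covariance of 0.0214, where 0.0275 was observed. So most of the covariance can come from the shared arrays, too few to be split, and the rest was not tested.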

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

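The tests of age, of hepatocyte share, of macrophage and lymphocyte markers, of the clock, of Hsd3b5 alone and of the percent called around Lmna were chosen only after the results were seen, and the other splits of the arrays and the share of calls around Lmna before.

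The KO minus HET change differed between diets for 8 genes by the interaction test. It was more positive on HFD for Slc16a5 (2.61), Guca2b (2.45), Nqo1 (2.05), Gstm3 (1.82), Pqlc3 (1.39), Kmt5a (1.25) and Tmem79 (1.18), and more negative for Tnfaip8l1 (-1.41). The sign changed for Kmt5a (-0.39 on chow, 0.86 on HFD), Tmem79 (-0.57, 0.62) and Tnfaip8l1 (0.57, -0.84). Of 100 splits of the arrays 4 gave at least 8 genes, the real one included, and the highest of the others gave 41, several times the real count, which points to a structure of the samples. These splits mix the diets within each genotype, so a diet effect in 1 genotype can be part of it.

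The same test differed between diets for 19 lists, given as mean log2 change of the members. Higher were NRF2 targets (0.64), lymphocyte markers (0.59), female-biased genes (0.51), cholangiocyte markers (0.44), p53 genes (0.44), lipid droplet genes (0.39), extracellular matrix (0.39), chemokines (0.36), macrophage markers (0.34), YAP and SRF targets (0.33), cell cycle (0.28) and fatty acid oxidation (0.22). Lower were hepatocyte identity (-0.15), glucose metabolism (-0.18), cholesterol synthesis (-0.25), pericentral genes (-0.44), the clock (-0.46), male-biased genes (-0.53) and interferon-stimulated genes (-0.76). With an estimated correlation the interferon list alone of these passed.

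Counts from other splits of the same arrays were as follows. For the mean of KO minus HET over both diets 1 of 100 splits, the real one, gave as many as 2091 genes and the highest other gave 515, so a chance split is unlikely. KO mice were older than HET mice on the same diet and shared no name letter with them, which these splits cannot tell from genotype. The other comparisons allow 10 splits each, too few for a share under 0.05. There the real and the highest other counts were 426 and 1 for KO against HET on chow, 1677 and 1 on HFD, 44 and 5 for diet in HET and 70 and 8 for diet in KO, with 1 split of 10 reaching the real count in each.

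Genes called between KO and HET livers over both diets may reflect the loss of Lmna, the older age of the KO mice or a change of cell types. If age acted in proportion to weeks, the change on HFD would be 0.388 times that on chow, and the ratio was 1.42 (jackknife SE 0.220), or 1.04 (SE 0.102) for the 367 genes called against WT. Some single lists were less precise and lay within 2 SE of 0.388, such as extracellular matrix (1.74, SE 0.896), macrophage (1.54, SE 0.775) and p53 genes (2.02, SE 1.13). Others lay further above it, such as NRF2 targets (1.99, SE 0.465), lipid droplet (1.43, SE 0.354) and cell cycle genes (1.38, SE 0.338). Of the called genes 0.81% lie among the 200 tested genes around Lmna, a share that could at most be 9.58% and so decides nothing. Among those 200 genes 8.50% were called, and among the others 9.44% (Fisher exact p = 0.807), so donor-strain DNA there stays open. A lower share of hepatocytes alone would raise the markers of other cells alike, but macrophage markers rose by 0.66 more than endothelial ones (SE 0.157). That argues against it as the only change. It cannot exclude a lower share beside other changes. Hepatocyte identity genes changed by -0.17 (SE 0.0219), endothelial markers by 0.14 (SE 0.0362) and cholangiocyte markers by 0.62 (SE 0.0951). Age in proportion for the lists within 2 SE, age acting in another way than by weeks, a lower share of hepatocytes beside other changes, and infiltration by macrophages, stay open.

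Interferon-stimulated genes were less raised in KO livers on HFD than on chow, and age, cell types or diet are candidate explanations. The ratio of the change on HFD to that on chow was 0.63 (jackknife SE 0.0661), against 0.388 for age in proportion to weeks. The list's level was -0.10 in WT and 0.07 in HET livers on chow, 0.41 in HET on HFD, 1.71 in KO on HFD and 2.13 in KO on chow, which is the order of age apart from the first 2, so age acting in another way stays open. From chow to HFD in KO livers the macrophage list changed by 0.48 (SE 0.243), the lymphocyte list by 0.45 (SE 0.177) and the interferon list by -0.42 (SE 0.102). A loss of cells would lower their markers at least as much as genes read partly from them. But the macrophage change lay above the interferon change by 0.90 (SE 0.266) and the lymphocyte change by 0.87 (SE 0.182). That argues against fewer such cells as a whole in KO livers. Loss of resident macrophages alone was not tested, and the interferon list's rise in HET livers (0.34) is not covered.

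Male-biased genes were lower in HET than WT livers on chow as a list, with 0 of 22 members called and the list's call lost with an estimated correlation (adjusted p = 0.255). The clock phase of the arrays, a single gene or the floxed copy may lie behind it. With the clock term the mean change went from -0.40 (SE 0.154) to -0.28 (SE 0.167), within 2 SE of 0, so clock phase and genotype cannot be told apart here. Without Hsd3b5 the list still passed at the preset correlation, with a camera adjusted p of 0.00109, so at that correlation 1 gene is not the whole cause. The male-biased level was -0.31 in HET F2 and 0.03 in HET P1, and 0.20 in WT G1.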

How the results depend on the processing

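The settings without HET arrays F1 and F2 and with a clock term were chosen only after results were seen, and all others before. Single genes and lists were followed through the settings only where the Results describe them with values for that comparison. Of the passing lists these were 2 of 18 for the mean over diets, 4 of 18 for diet in KO and 2 of 19 for the interaction. Followed genes that had passed kept direction and call in 4701 of 5497 fits, lost the call in 782 and turned in 14. Followed lists that had passed kept it in 1222 of 1305, lost it in 72 and turned in 11. Followed lists that had not passed turned in 3 of 519 fits. The turn of a list was judged by its camera direction, relative to other genes, and not by the sign of its mean. In fits where a group keeps 1 array, that array is assumed to vary like the others.

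Age was also fitted as a linear term. Its slope rests on differences of at most a few weeks within 3 groups and is extended over 13.3 weeks, and it rests on the same arrays that differ in clock phase. With it 201 genes passed for KO against HET on chow, 124 for KO against WT, 1 for HET against WT, 249 for KO against HET on HFD, 211 for the mean over diets, 271 for diet in HET, 132 for diet in KO and 206 for the interaction. Lists passing became 9 for KO against WT, 3 for HET against WT, 13 for KO against HET on HFD, 9 for the mean over diets and 14 for diet in HET. The correlation of genotype effects between diets became 0.866 and that of genotype with diet effect 0.894, since 1 slope enters both sides.

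Results that turned with the age term follow, and their cause was not tested. Those that passed the other way were, for KO against HET, the extracellular matrix (adjusted p = 0.0132), stellate cell (0.0195) and macrophage lists (0.00153) on chow and the xenobiotic list on HFD (2.56e-04). All followed genes and lists that turned, passing or not, are given next by comparison. Other lists were not checked for a turn. For KO against HET on chow they were Hsd3b5 (5.62), Igfals (0.70), Nqo1 (-1.09) and the lists of male-biased genes (0.47), NRF2 targets (-0.13), extracellular matrix (-1.905), stellate cells (-1.86) and macrophages (-2.15). For KO against WT they were Clec2h (0.20), Foxq1 (0.25), Mup21 (0.91), Selenbp2 (2.57), Ugt2b38 (1.51), Zfp872 (1.78) and the male-biased list (0.06). For KO against HET on HFD they were Bcl6 (0.82), Cyp4a12b (-0.029) and the lists of fatty acid synthesis (0.14), xenobiotic genes (0.81), macrophages (-0.11), lymphocytes (-0.24) and pericentral genes (0.17). The bile acid list turned there only in its camera direction, and its mean stayed negative (-0.025). For the mean over diets they were Cd163 (0.03), Hsd3b5 (1.39) and Selenbp2 (1.57), and for diet in HET the xenobiotic list (0.33).

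Fitting only the groups compared, with fewer arrays, gave 216 genes for KO against HET on chow, 162 for KO against WT, 3 for diet in HET and 45 for diet in KO. An adjusted p under 0.01 gave 157, 151, 705 for KO against HET on HFD, 1001 for the mean over diets, 13 for diet in HET, 9 for diet in KO and 1 for the interaction. A fold minimum of 1.5 gave 1122 for the mean over diets. Chow controls as 1 group gave 670 for KO on chow. Testing all probe sets gave 26 for diet in HET, 17 for diet in KO and 0 for the interaction.

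For the settings below the cause was not tested. Array weights gave 67 genes for diet in HET, 221 for diet in KO and 29 for the interaction, and 3 lists for HET against WT. The trended prior gave 110 for diet in KO, 24 for the interaction and 2 lists for HET against WT. The filter on dim probe sets gave 1 gene and 2 lists for HET against WT, 107 for diet in KO and 29 for the interaction. Median centring gave 20 for the interaction and 2 lists for HET against WT, and a second quantile normalization 1 gene and 2 lists there. The name letter as a block gave 44 for diet in KO and 5 for the interaction. The clock term gave 128 for diet in KO and a correlation of genotype with diet effect of -0.093. Without it the other pairs of the Results gave 0.160 (no array shared) and 0.287 (HET chow arrays shared).

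Without HET arrays F1 and F2, 143 genes passed for KO against HET on chow, 6 for HET against WT and 1 for the interaction, with 2 lists for HET against WT and 8 for the interaction, and the lymphocyte list turned for KO against HET on chow (0.32). Camera with an estimated correlation left 1 list for KO against HET on chow, 7 for KO against WT, 0 for HET against WT, 11 for KO against HET on HFD, 11 for the mean over diets, 0 for diet in HET, 0 for diet in KO and 1 for the interaction. Fry gave 0 for HET against WT, 5 for diet in HET, 6 for diet in KO and 3 for the interaction.

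Leaving out 1 array in turn gave 199 to 520 genes for KO against HET on chow, 154 to 411 for KO against WT, 0 to 10 for HET against WT, 971 to 1788 for KO against HET on HFD, 1473 to 2034 for the mean over diets, 13 to 164 for diet in HET, 13 to 119 for diet in KO and 0 to 43 for the interaction. Lists passing ranged over 15 to 18, 16 to 19, 1 to 7, 16 to 22, 17 to 19, 8 to 12, 10 to 20 and 9 to 21 in the same order. The correlation of genotype effects between diets ranged from 0.493 to 0.615 and that of genotype with diet effect from -0.047 to 0.041. The dim Lmna probe set, at 3.67 to 4.50 over a median array value of 2.21 to 2.30, limits how closely its change can be read.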
